A study of Xenopus laevis with 6 samples.

How the data were processed

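Poly(A)-selected, strand-specific RNA libraries were made from whole Xenopus laevis embryos. The 6 libraries fall into 2 groups of 3 by their titles. One group came from intact embryos. The other came from half-size embryos, which grew from single blastomeres after the first 2 cells of an embryo had been separated. The labels describe the half-size embryos of each replicate as siblings of the intact embryos of that replicate, and name 3 biological replicates.

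The authors deposited a table of read counts, whole numbers per gene and library that were not normalized. TopHat2, HTSeq and DESeq are named in the submitters' processing notes, without versions or roles. The genome build and the gene annotation behind the counts are not given in the sources used here, so no coordinates are printed. The count table lists 45090 genes, of which 10042 had no count in any library and 27585 carry only a gene model or locus identifier. Most duplicated genes of this allotetraploid species are listed as 2 homeologs, with the endings L and S, and reads shared between near-identical copies may have been split between them in a way that the sources used here do not state. Per the labels' protocols the kit keeps strand, and whether the counting used strand is not given in the sources used here.

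The authors also deposited a table of their own comparison of the 2 groups, with 19518 genes. In the authors' deposited table the mean levels are a signal, calculated as means of counts divided by size factors, which recomputing them from the counts bore out. In the authors' deposited table the fold change is a linear ratio of the half-size mean to the intact mean. The log2 fold change in the authors' deposited table is the log2 of that ratio. The authors' deposited table gives a p-value and an adjusted p-value per gene. From this table, 10 repeated gene names were left out.

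Total counts ranged from 20069300 to 29284864 per library, so that 1 count equalled between 0.0341 and 0.0498 CPM (counts scaled by library size to CPM units). Pearson's chi-square per degree of freedom between any 2 libraries, over genes with at least 20 counts in the pair, lay between 13.3 and 91.3, so no 2 libraries differed by as little as sampling noise and each was counted as 1 sample.

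Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, on the counts as deposited, after TMM normalization and the filterByExpr filter, which kept 21673 genes. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The comparison fixed before the data were examined had the group as its only term. The fit with the replicate number as a block was fixed at the same time as an alternative, and is called the paired fit here. The numbers pair the libraries: the labels name siblings, and after subtraction of the group means the deviations of libraries with the same number correlated at 0.75, 0.82 and 0.68 over genes, against −0.55 to −0.20 for libraries with different numbers. Subtracting group means ties these values together. Positive correlations within numbers push those between numbers below 0, so the negative values add no separate support. The first 2 principal components of log2 CPM, with 49.5% and 27.4% of the variance, separated the replicate numbers, and the third, with 13.0%, separated the groups. On each of the first 2 components the half-size library also lay on the same side of its intact sibling in all 3 pairs. Because pairing changed the calls, counts of genes called are given for both fits. Log2 fold changes and adjusted p-values of single genes are from the paired fit unless stated otherwise. List means and list tests are from the fit without pairing unless stated otherwise. CPM values were computed with TMM-scaled library sizes and are given as mean ± SD over 3 libraries. A log2 fold change is given with its standard error, derived from the F statistic.

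Both fits were tested on simulated counts with known changes, drawn with a shared component per pair. Of the genes made to differ 2-fold, the fit without pairing recovered 2.04% and the paired fit 74.5%. At 4-fold the shares were 44.8% and 100%. The fit without pairing made 0 false calls. The paired fit made 15, beside the 73 of 98 genes it recovered at 2-fold and the 96 of 96 at 4-fold. Its false calls were thus a larger share of its calls than the adjusted p threshold stands for. Calls of the paired fit on the real counts may likewise hold more false ones than that threshold states.

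Gene lists were fixed before the data were examined and were matched by symbol, through synonyms in the reference table of the assembly Xenopus_laevis_v10.1 where a symbol was not found. Of the 29 lists, 28 had at least 4 tested members. Matching was partial: it found, for example, 14 of the 26 symbols of the multiciliated cell and ionocyte list, 26 of 47 of the protease list, 20 of 28 of the ventral BMP list and 22 of 27 of the epidermis list, and the results of a list cover its matched symbols only. The mitochondrially encoded list had 0 of its 14 symbols in the table and was not tested. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. Camera with a correlation estimated for each list and fry were the alternatives. With an estimated correlation, camera rests on the few residual degrees of freedom of 6 libraries, fewer still with the block. It could therefore call almost nothing: its lowest adjusted p over the lists was 0.21 without pairing and 0.52 with pairing. Camera sets a list against the other genes tested, while fry asks whether its genes moved, on balance, one way.

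Genes were named by rules fixed before the data were examined: the 10 genes per direction with the largest change past the threshold of the fit without pairing, or, where fewer than 5 passed, the 5 with the smallest p-value, in either case with a gene symbol rather than a model or locus identifier and with CPM that did not overlap between groups and averaged at least 1, the 4 members with the smallest p-value of each list called, and, whatever their p-value, the members of the dorsal-ventral patterning network mmp3, chrd, nog, bmp4, szl, admp, bambi and ventx. Added after the data were seen were the 10 genes per direction, again with a gene symbol, with the largest change past the threshold in the paired fit and one sign in all 3 pairs, and the 4 members with the smallest paired p-value of each list with a paired call or a member past the threshold. Other alternatives were size factors from DESeq2 1.42.0, upper-quartile normalization, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2, limma-voom, homeologs summed, other thresholds, and leaving out each library. The same settings within the paired fit, leaving out each pair in turn, were added after the data were seen. A check of GC content or gene length was not made, as no genome was used here.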

Results

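Gene expression was measured by RNA sequencing in whole embryos of Xenopus laevis, the African clawed frog, at late gastrula (Nieuwkoop and Faber stage 12.5). Half-size embryos, each grown from 1 of the first 2 blastomeres after their separation, were compared with intact siblings. Each group had 3 libraries, numbered 1 to 3, and libraries with the same number came from siblings. Total counts were 24509421, 29284864 and 20069300 in intact replicates 1, 2 and 3, and 23047162, 20205384 and 26097821 in half-size replicates 1, 2 and 3. Replicate number accounted for more of the variance between libraries than the group did.

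The comparison asked which genes differ in expression between embryos of normal and of reduced size. Among genes that had a symbol, averaged at least 1 CPM and passed the threshold in the paired fit, the largest fall in half-size embryos was that of mmp3.L, which encodes a secreted matrix metalloproteinase. It averaged 7.71 ± 3.24 CPM (SD, n = 3) in intact and 0.637 ± 0.620 CPM (SD, n = 3) in half-size libraries, 13.2-fold lower in the paired fit (log2 fold change −3.72 ± 0.29 SE, adjusted p = 0.000246; −4.39 without replicate 2). In the edgeR fit without pairing mmp3.L did not pass the threshold (log2 fold change −3.62, unadjusted p = 0.000955, adjusted p = 0.9998). Without pairing DESeq2 called it (adjusted p = 1.70e-05) and limma-voom called 0 genes. In the paired fit 21 of 43 epidermis genes fell, among them tp63.S, and 7 rose, and 12 of 25 genes of multiciliated cells and ionocytes fell, among them ccno.S and foxj1.2.L. In that fit the direction of these lists was not called with an estimated correlation (adjusted p = 0.55 and 0.52). That form of the test had too few degrees of freedom here to decide. The cytoskeletal actin homeologs actg1.S and actg1.L rose 2.88-fold and 2.30-fold in the paired fit (adjusted p = 0.000187 and 0.000246), and slc16a6-like.L rose 4.49-fold (adjusted p = 8.00e-05). Of 33 genes of the dorsal organizer list 10 rose in the paired fit, frzb.L and chrd.1.L.g among them (list adjusted p = 0.52 with an estimated correlation in that fit). Of 43 genes of the ventral BMP list 11 fell in the paired fit, bambi.L and bambi.S among them, 2 rose and 30 did not pass (list adjusted p = 0.55 with an estimated correlation in that fit).

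Whether single genes passed the threshold depended on the pairing of siblings. With the group as the only term, edgeR called 0 of 21673 genes (smallest adjusted p = 0.137), while 776 genes had an unadjusted p under 0.05, 271 higher and 505 lower in half-size embryos, and limma-voom called 0 genes and DESeq2 42. In the paired fit, with the replicate number as a block, edgeR called 1283 genes, 431 higher and 852 lower. Of these, 776 differed by at least 1.5-fold, 200 higher and 576 lower, where the fit without pairing called 0. At 2-fold or more, 47 genes were higher and 258 lower. The biological coefficient of variation was 34.1% without pairing and 11.4% with it. The 42 genes called by DESeq2 without pairing, 13 higher and 29 lower, were all called with the same sign by the paired edgeR fit. CPM ranges of the 2 groups did not overlap for 1960 genes, 9.04% of those tested. Chance would give 10% for 6 exchangeable libraries, which these, deviating in pairs, were not, so the count is no measure of how many genes differed. Without replicate 3, the paired fit called 507 genes, 165 higher and 342 lower, and 415 at 1.5-fold or more. Without replicate 1 it called 666 higher and 805 lower, and without replicate 2 it called 305 higher and 750 lower.

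**Figure D1:**
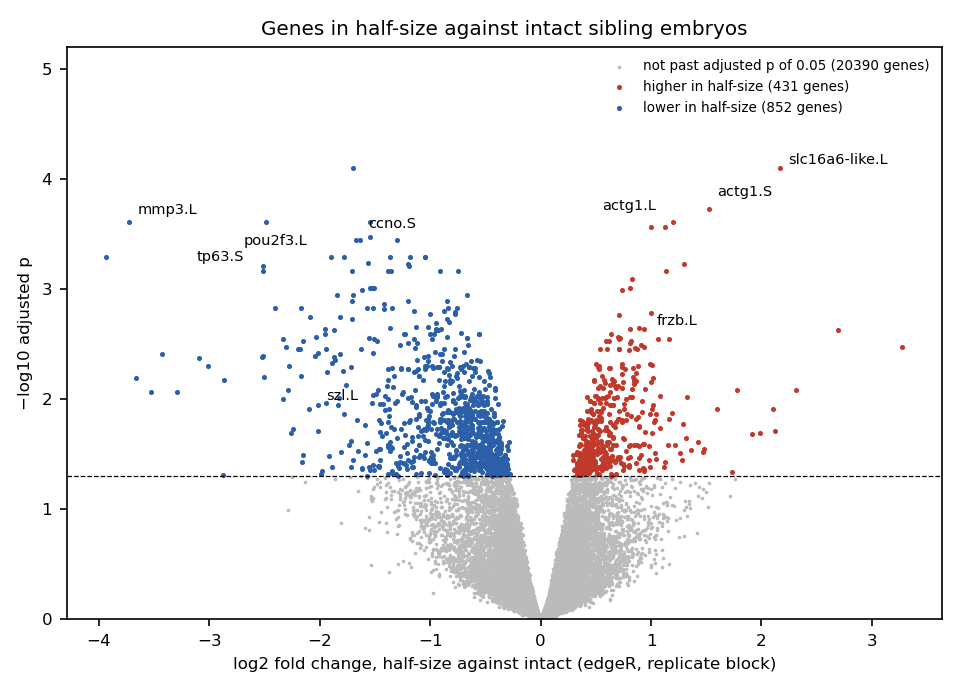
Each point is 1 of 21673 genes, with its log2 fold change in half-size against intact embryos from the paired edgeR fit on the x axis and −log10 of its adjusted p on the y axis. Red points are the 431 genes called higher and blue points the 852 called lower, and the dashed line marks an adjusted p of 0.05.

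Among the genes higher in half-size embryos that had a symbol, no overlap between groups and a mean of at least 1 CPM, those with the smallest p without pairing were actg1.S, actg1.L, slc16a6-like.L, tspan1.L, a tetraspanin gene, and klf11.L, a zinc finger transcription factor gene. The paired log2 fold changes of actg1.S, actg1.L, slc16a6-like.L and klf11.L were 1.53 ± 0.11, 1.20 ± 0.09, 2.17 ± 0.14 and 0.88 ± 0.12 (SE), and tspan1.L rose from 32.6 ± 2.82 to 65.9 ± 12.1 CPM (SD, n = 3). The homeolog slc16a6-like.S had a paired log2 fold change of 2.69 ± 0.34 (SE) at a lower level, 0.532 ± 0.448 against 3.21 ± 1.64 CPM (SD, n = 3). Other large paired rises were those of nefl.L, a neurofilament gene (log2 fold change 1.78, adjusted p = 0.00822), and rgs2.L, a regulator of G protein signalling (1.32, adjusted p = 0.00958). The nefl.L call was lost by paired DESeq2 (adjusted p = 0.0518). The same rule also gave nov.L (paired log2 fold change 1.99), chst1.S (1.60), nkx1-2.L (1.48), nptx2.S (1.42) and pcdha13.S (1.28). The calls of nov.L, nptx2.S and pcdha13.S were lost without replicate 1. Those of nkx1-2.L, nptx2.S and pcdha13.S were lost without replicate 3.

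Among the lower genes, pou2f3.L, which encodes a POU-domain transcription factor, averaged 11.1 ± 0.811 CPM in intact and 2.98 ± 0.543 CPM in half-size libraries (SD, n = 3), with a paired log2 fold change of −1.90 ± 0.17 (SE). The chemokine gene cxcl12.L averaged 153 ± 11.1 and 89.6 ± 5.57 CPM (SD, n = 3), with a paired log2 fold change of −0.77 ± 0.09 (SE). Paired log2 fold changes below −2 were also found for ankrd37.S (−3.43), cldn1.S, which encodes a tight junction claudin (−3.01), nr3c2.L (−2.88), cdc20b-like.L (−2.52), tp63.S (−2.51), the endodermal and endothelial transcription factor gene sox7.S (−2.51), gng13.S (−2.33), foxj1.2.L (−2.31) and myb.S (−2.18). Leaving out 1 pair kept the calls of mmp3.L, ankrd37.S, sox7.S, foxj1.2.L and myb.S but moved their folds by over 1.5 times. Without replicate 2 the log2 fold change was −4.39 for mmp3.L, −3.57 for sox7.S, −3.11 for foxj1.2.L and −2.77 for myb.S. Without replicate 1 it was −4.15 for ankrd37.S, and without replicate 3 it was −2.64 for ankrd37.S and −1.83 for sox7.S. The value for nr3c2.L rested on 1 pair, with log2 ratios of −1.06, −0.32 and −5.40 in pairs 1, 2 and 3. Its call, with an adjusted p of 0.0492, was lost without replicate 3 (log2 fold change −0.86, adjusted p = 0.352; −4.24 without replicate 1), by paired DESeq2 (adjusted p = 0.396) and with DESeq2's size factors (adjusted p = 0.0511).

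**Figure D2:**
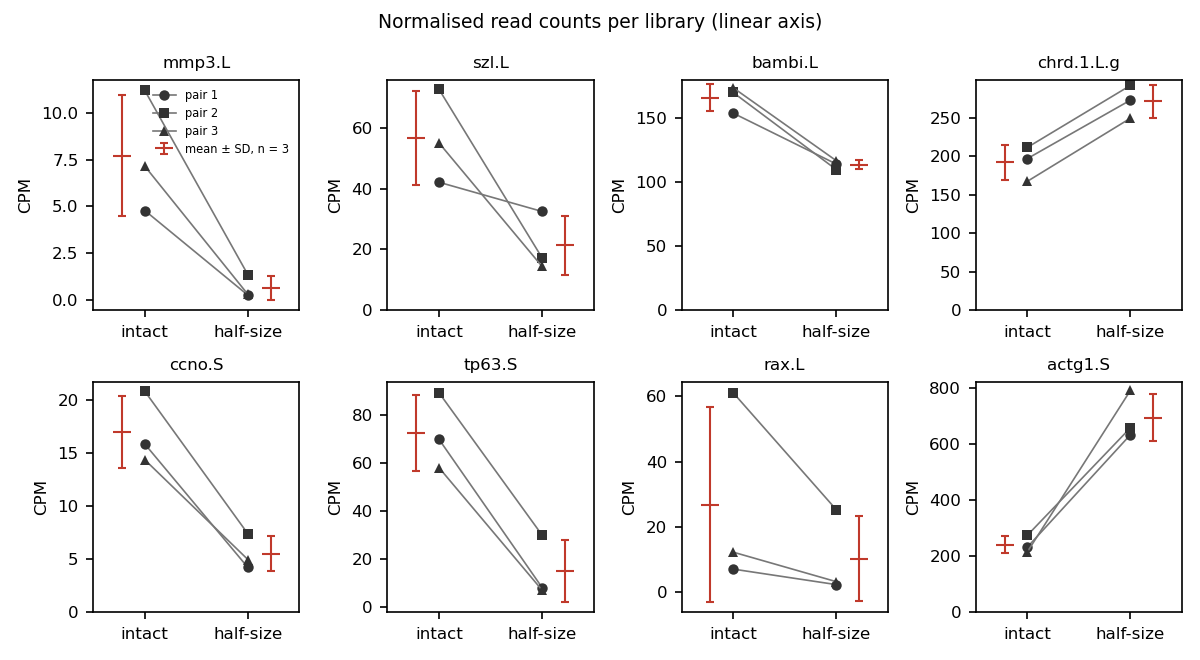
Normalised read counts (CPM, linear y axes) of 8 genes in each library, with grey lines joining siblings and red bars giving the mean ± SD of 3 libraries per group. In all 3 pairs mmp3.L, szl.L, bambi.L, ccno.S, tp63.S and rax.L were lower, and chrd.1.L.g and actg1.S higher, in the half-size library.

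The network that sets the dorsal-ventral axis, in which BMP signals on the ventral side are held off by antagonists secreted from the dorsal organizer, was read gene by gene. Chordin, a BMP antagonist, was counted as chrd.1.L.g and chrd.2.L.g, which rose from 192 ± 22.5 to 271 ± 21.3 CPM and from 139 ± 16.6 to 189 ± 22.7 CPM (SD, n = 3; paired adjusted p = 0.00477 and 0.0105). The BMP pseudoreceptor homeologs bambi.L and bambi.S fell from 166 ± 10.5 to 113 ± 3.51 CPM and from 94.6 ± 5.14 to 61.9 ± 4.27 CPM (SD, n = 3; paired adjusted p = 0.00454 and 0.00517). Sizzled, a secreted inhibitor of chordin-cleaving proteases, fell from 29.5 ± 3.13 to 14.9 ± 5.75 CPM for szl.S (SD, n = 3; paired adjusted p = 0.0121) and from 56.6 ± 15.4 to 21.4 ± 9.73 CPM for szl.L (SD, n = 3; paired adjusted p = 0.0111). The szl.L call was lost without replicate 3 (adjusted p = 0.0604) and by paired DESeq2 (adjusted p = 0.0602). No bmp4, nog, admp or ventx gene passed the threshold in either fit. The paired log2 fold changes were −0.25 and −0.30 for bmp4.L and bmp4.S, 0.38 and −0.36 for nog.L and nog.S, 0.28 and 0.17 for admp.L and admp.S, and between −1.25 and 0.10 for the 7 ventx genes tested.

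Genes were then grouped by lists fixed in advance. The multiciliated cell and ionocyte list had the lowest mean, −0.75 log2 units over 25 tested genes, and was lower than other genes by camera (adjusted p = 4.18e-08; adjusted p = 0.21 with an estimated correlation). In the paired fit 12 of its members fell and 0 rose over all genes tested, and 14 fell and 1 rose adjusted over the list alone. The falls included ccno.S, a cyclin-family gene of centriole multiplication, from 17.0 ± 3.38 to 5.54 ± 1.66 CPM (SD, n = 3), and ccno.L, foxn4.S, the ciliary regulator foxj1.2.L and foxi1.L, the ionocyte transcription factor gene, had paired log2 fold changes of −1.36, −1.78, −2.31 and −1.55. Non-neural epidermis had a mean of −0.37 over 43 genes (camera adjusted p = 0.000228; adjusted p = 0.37 with an estimated correlation). Of its members 21 fell and 7 rose in the paired fit, and 24 fell and 8 rose adjusted over the list alone. Among the falls were tp63.S, a regulator of basal epidermal cells, from 72.6 ± 15.8 to 15.2 ± 12.9 CPM (SD, n = 3), the keratin krt12.S (paired log2 fold change −0.91), grhl3.S (−0.75) and the intelectin itln1.L (−1.55). The rises included cldn6.1.S, a tight junction claudin gene (paired log2 fold change 0.71).

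The organizer and dorsal midline list was higher, with a mean of 0.32 over 33 genes (camera adjusted p = 1.60e-05; adjusted p = 0.37 with an estimated correlation). In the paired fit 10 members rose and 0 fell, and 16 rose adjusted over the list alone. The Wnt antagonist frzb.L rose from 52.3 ± 4.22 to 103 ± 30.2 CPM (SD, n = 3), with frzb.S, lhx1.L and lhx1.S at paired log2 fold changes of 1.06, 0.83 and 0.81. The ventral BMP list was lower, with a mean of −0.26 over 43 genes (camera adjusted p = 1.43e-05; adjusted p = 0.21 with an estimated correlation). Of its members 11 fell in the paired fit and 17 adjusted over the list alone, and the 2 that rose by either count were wnt8a.S and wnt8a.L, a Wnt ligand of the ventral and lateral mesoderm (paired log2 fold changes 0.68 and 0.54).

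FGF response genes were higher, with a mean of 0.27 over 36 genes (camera adjusted p = 5.86e-06; adjusted p = 0.21 with an estimated correlation). In the paired fit 13 rose and 0 fell, and 22 rose adjusted over the list alone, among them egr1.S, egr1.L, the MAP kinase phosphatase gene dusp6.S and spry1.L, with paired log2 fold changes of 1.01, 0.86, 0.59 and 0.58. Early gastrula zygotic genes had a mean of 0.40 over 31 genes (camera adjusted p = 5.86e-06; adjusted p = 0.54 with an estimated correlation). Of these 9 rose and 1 fell in the paired fit, and 19 rose and 1 fell adjusted over the list alone. The T-box gene eomes.S rose from 29.3 ± 13.7 to 52.8 ± 18.4 CPM (SD, n = 3), pou5f3.2.L from 329 ± 148 to 547 ± 229 CPM (SD, n = 3), and gs17.S was the member that fell (paired log2 fold change −0.94). Immediate early and wounding genes had a mean of 0.27 over 41 genes (camera adjusted p = 8.96e-05; adjusted p = 0.42 with an estimated correlation). Of these 5 rose and 1 fell in the paired fit, and 10 rose and 1 fell adjusted over the list alone. They share egr1 with the FGF list, and ier2.L had a paired log2 fold change of 0.73. By pair the list's mean was 0.42, 0.36 and 0.03. The list's call was lost without half-size replicate 2 (adjusted p = 0.0704).

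The cell cycle list had a mean of 0.16 over 75 genes (camera adjusted p = 0.000735; adjusted p = 0.37 with an estimated correlation), with 6 rises and 0 falls in the paired fit, and 19 rises and 1 fall adjusted over the list alone. The phosphatase gene cdc25b.S rose from 22.0 ± 2.73 to 38.6 ± 2.08 CPM and the ribonucleotide reductase gene rrm1.L from 47.2 ± 0.952 to 65.9 ± 2.58 CPM (SD, n = 3). The ribosomal protein list had a mean of −0.17 over 54 genes (camera adjusted p = 6.05e-05; adjusted p = 0.54 with an estimated correlation), with 3 falls in the paired fit and 7 adjusted over the list alone, among them that of rpl38.L (paired log2 fold change −0.57). The rpl38.L call was lost without replicate 3 (adjusted p = 0.0898), and the list's call without intact replicate 2 (adjusted p = 0.0677) and without half-size replicate 3 (adjusted p = 0.151). The germ plasm and maternal list had a mean of 0.19 over 33 genes (camera adjusted p = 0.0244; adjusted p = 0.54 with an estimated correlation), with zpax.L as its 1 rise in the paired fit and adjusted over the list alone, a call lost without replicate 3 (adjusted p = 0.103). The germ plasm list's call was lost without intact replicate 2 (adjusted p = 0.352) and without half-size replicate 3 (adjusted p = 0.496), and with pairing without replicate 3 (adjusted p = 0.0906).

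Camera with the preset correlation thus called 10 of 28 lists, 6 higher and 4 lower. Lists share members, so these calls are not independent results. For example, eomes.S is in the mesoderm, nodal and early gastrula lists, and frzb.L in the organizer and endoderm lists. The calls depended on the form of the test: camera with an estimated correlation called 0 lists and fry called 0. A wrong grouping of the 6 libraries reached 13 list calls, but it set pair 2 against pair 3, so differences between replicates entered it. Without pairing, the estimated correlations of the 10 lists called lay between 0.035 (ventral BMP) and 0.58 (early gastrula), all above the preset 0.01. The p-values with the preset may therefore be too small. In the paired fit the size of the correlation alone did not account for the loss, as an estimate also leaves far fewer degrees of freedom. There the immediate early list had an estimated correlation of 0.0084, below the preset 0.01. Its camera adjusted p nevertheless went from 0.000766 to 0.52. A list missed with an estimated correlation is therefore not shown to be unchanged. With pairing 13 lists were called, the added ones being mesoderm (adjusted p = 0.0298, against 0.0598 without pairing), endoderm (adjusted p = 0.0298 against 0.0725) and the nodal pathway (adjusted p = 0.0336 against 0.163). With an estimated correlation in the paired fit these 3 had an adjusted p = 0.55, 0.52 and 0.52. Without replicate 3 their paired calls were lost (adjusted p = 0.0661, 0.0768 and 0.0768), the mesoderm call also without replicate 2 (adjusted p = 0.162), and the mesoderm and endoderm calls also with homeologs summed (adjusted p = 0.128 for each).

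**Figure D3:**
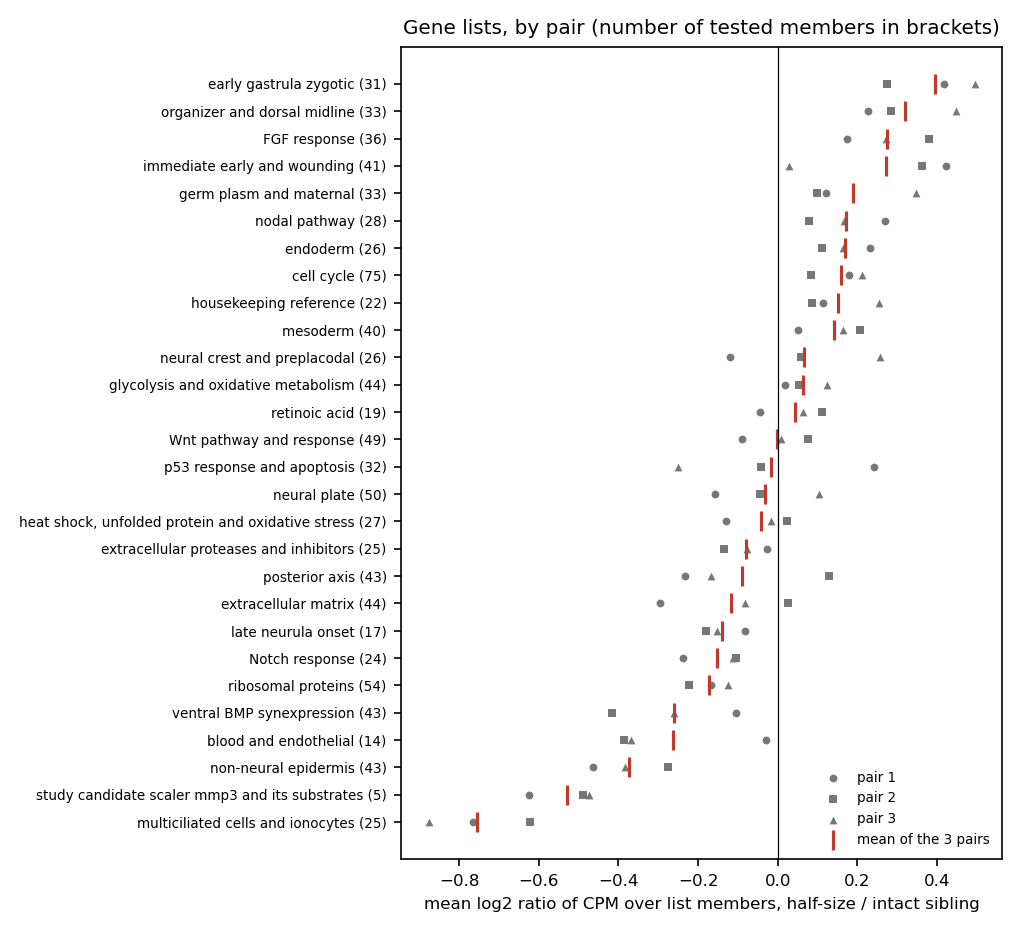
Mean log2 ratio of CPM, half-size over intact sibling, over the tested members of each of 28 gene lists (x axis), with 1 grey marker per pair and a red bar for the mean of the 3 pairs. The multiciliated cell list lay between −0.88 and −0.62 and the early gastrula list between 0.27 and 0.49 in the 3 pairs.

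In the mesoderm list 6 members rose and 0 fell in the paired fit, and 16 rose and 2 fell adjusted over the list alone. In the endoderm list 3 rose and 0 fell, with 6 and 1 adjusted over the list alone. In the nodal list 7 rose and 1 fell, with 10 and 3 adjusted over the list alone. The genes eomes.S and eomes.L were among the rises of the mesoderm and nodal lists, frzb.L and frzb.S among those of the endoderm list, and the TGF-beta ligand gene gdf3.S (paired log2 fold change 0.64) among those of the nodal list. The neural plate list was not called (adjusted p = 0.0598) and its mean of −0.03 had the opposite sign to its median of 0.14 and to the direction of the test, which was up. There, 8 members fell and 2 rose in the paired fit, and 10 fell and 9 rose adjusted over the list alone. The eye field genes rax.L, rax.S and six3.L had paired log2 fold changes of −1.57, −1.38 and −1.42, and foxd4l1.1.L of 0.49. Expression of rax.L differed widely between replicates, at 26.8 ± 29.8 CPM in intact and 10.2 ± 13.0 CPM in half-size libraries (SD, n = 3). The six3.L call was lost by paired DESeq2 (adjusted p = 0.0598) and that for foxd4l1.1.L without replicate 2 (adjusted p = 0.0665).

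The list of mmp3 and its substrates, which the study chose on these samples and which is therefore no independent evidence of direction, was not called (adjusted p = 0.570). Its mean of −0.53 had the opposite sign to its median of 0.38 and its test, since mmp3.L fell while both chordin genes rose in the paired fit (2 rises and 1 fall), and adjusted over the list alone 3 of 5 members rose and 1 fell. Extracellular proteases and inhibitors were not called either (adjusted p = 0.456, mean −0.08, median 0.09, test up), with adamts1.L among 3 rises and mmp3.L among 2 falls in the paired fit, counts that were the same adjusted over the list alone.

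The other lists were not called in either fit. In the paired fit over all genes tested, neural crest and preplacodal genes (camera adjusted p = 0.614) had 2 rises and 2 falls, with a mean of 0.07, a median of −0.02 and an upward test, and foxd3.L had a paired log2 fold change of 0.92. Posterior axis genes (adjusted p = 0.758) had 4 rises and retinoic acid genes (adjusted p = 0.570) 2, with the retinaldehyde dehydrogenase gene aldh1a2.S at a paired log2 fold change of 0.49. Wnt pathway genes (adjusted p = 0.614) had 7 rises and 4 falls, with a mean of −0.0020, a median of 0.04 and an upward test. Notch response genes (adjusted p = 0.189) had 2 rises and 3 falls, with hes5.1.S at a paired log2 fold change of −0.92. The late neurula onset list (adjusted p = 0.508) had 0 of 17 members past the threshold. Heat shock and stress genes (adjusted p = 0.364) had 1 rise and 1 fall. In the p53 list (adjusted p = 0.823, mean −0.02, median 0.06, test up) 2 members rose and 1, ccng2.S, fell, with plk2.L at a paired log2 fold change of 0.81. Blood and endothelial genes (adjusted p = 0.852) had 3 falls, extracellular matrix genes (adjusted p = 0.614) 2 rises and 2 falls, glycolysis and oxidative metabolism genes (adjusted p = 0.215) 2 falls, and housekeeping genes (adjusted p = 0.163) 4 rises. Adjusted over the list alone, rises and falls in these lists numbered 2 and 3, 4 and 0, 2 and 1, 9 and 6, 2 and 3, 1 and 4, 1 and 1, 4 and 5, 0 and 3, 2 and 4, 0 and 2, and 4 and 2, in the order given.

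The authors' deposited table holds their own comparison of the same groups. In the authors' deposited comparison, 21 genes had an adjusted p under 0.05, 4 higher and 17 lower in half-size embryos, among them mmp3.L (log2 fold change −3.59, adjusted p = 0.00258), actg1.S, tp63.S, ccno.S, myb.S and pou2f3.L. Of those 21 genes, the edgeR fit without pairing called 0, DESeq2 without pairing 16 and the paired edgeR fit 21, all with the same sign as in the authors' deposited table. Across the 19508 genes in both tables, which are not independent replicates, log2 fold changes from edgeR without pairing and from the authors' deposited table had a Spearman correlation of 0.9998.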

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

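The settings within the paired fit were added after the data were seen; all others were fixed before the data were examined. Without pairing, the count of genes called stayed at 0 under every normalization, filter and threshold tried, with limma-voom, with homeologs summed and without each library in turn. It was 42 with DESeq2, at 1.5-fold or more also 42, and 1283 and 776 with the replicate block; in simulated counts the fit without pairing recovered few 2-fold changes. Agreement with the authors' deposited table was 0 genes without pairing, 16 by DESeq2 and 21 with the replicate block. List calls numbered 10 to 15 under the other settings without pairing, and 13 with the replicate block, but 0 with an estimated correlation and 0 by fry, with or without the block. Beyond gene counts, the block changed the calls of the mesoderm, endoderm and nodal lists and of no other list.

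Within the paired fit the count was between 1044 and 1364 under 2 other normalizations, the stricter filter, DESeq2, limma-voom and summed homeologs. It was 2568 without a filter (1331 at 1.5-fold or more), where more genes of low count were tested and the cause was not tested further, 2463 at an adjusted p under 0.1 and 337 under 0.01. Leaving out pairs gave 507 to 1471 genes, and 415 to 933 at 1.5-fold or more, the lowest both times without replicate 3. Without replicates 1, 2 and 3, 907, 795 and 462 of the 1283 genes were called with the same sign. Of 106 named genes past the threshold in the paired fit, 92, 82 and 67 kept their call without replicates 1, 2 and 3, with 1 pair fewer to test; paired DESeq2 kept 84 of the 93 to which it gave an adjusted p. Size factors from DESeq2 and upper-quartile normalization shifted the log2 fold changes of all genes by a median of at most 0.00977 in either fit. Total counts of at least 20069300 per library limit what can be said of genes near 1 CPM, such as nog.S. Several of the largest falls also ended below 1 CPM. Means in half-size libraries were 0.637 CPM for mmp3.L, 0.219 for ankrd37.S, 0.246 for cldn1.S, 0.457 for cdc20b-like.L and 0.446 for gng13.S. The size of these falls is therefore uncertain.

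Signs reversed for named genes that did not pass the threshold in the fit concerned. Leaving out 1 library at a time without pairing gave log2 fold changes of −0.050 to 1.06 for mmp14.L, −3.30 to 0.10 for rax.L, −0.70 to 2.14 for hsp90aa1.1.L, −4.63 to 0.71 for spib.L, −2.94 to 0.33 for spib.S, −2.11 to 0.62 for sparc.L and −1.83 to 0.66 for fbn3.S, with the lowest value without half-size replicate 2 and the highest without intact replicate 2. The range was −0.033 to 0.92 for mdh2.L, −0.024 to 0.66 for admp.L, −0.24 to 0.66 for admp.S, −0.73 to 0.015 for nog.S, −0.45 to 0.080 for ventx1.1.L, −0.16 to 0.52 for ventx1.2.L and −0.33 to 0.17 for ventx1.2.S. Without a library left out, ventx1.2.S had −0.025 with limma-voom and −0.013 with the replicate block. Leaving out 1 pair at a time in the paired fit gave −0.39 to 0.045 for ventx1.1.S, −0.051 to 0.31 for ventx1.2.L and −0.17 to 0.20 for ventx1.2.S, which had 0.0025 there without a filter. For mmp14.L, rax.L, hsp90aa1.1.L, spib.L, spib.S, sparc.L and fbn3.S, replicate 2 had the highest CPM in both groups. Leaving out only 1 library of that pair thus removed the highest value of 1 group alone. None of these genes reversed sign in the paired fit. The cause was not tested further.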

Other observations

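Genes often used as expression references were among those that moved. In the housekeeping list, actg1.S, actg1.L, odc1.L and odc1.S rose in the paired fit by 1.53, 1.20, 0.48 and 0.39 on the log2 scale, actg1.S from 241 ± 30.4 to 693 ± 84.8 CPM and odc1.L from 1198 ± 290.1 to 1648 ± 191 CPM (SD, n = 3). The odc1.L and odc1.S calls were lost without replicate 3 (adjusted p = 0.0533 and 0.0953). The prolyl hydroxylase homeologs egln3.L and egln3.S fell, with paired log2 fold changes of −1.09 and −0.91, calls that were also lost without replicate 3 (adjusted p = 0.0534 and 0.185), and for egln3.S without replicate 2 (adjusted p = 0.169).

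Of the tests that follow, those of library size, of a uniform epidermal share and of other groupings were chosen only after the result was seen. Tests of stage and of homeologs were written down before their statistics were computed, but after tables of the leading genes, with eomes, frzb and the actg1 homeologs among them, had been seen.

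The mean of the epidermis list and that of the multiciliated cell list were below 0 in all 3 pairs, with 21 of 43 and 12 of 25 members lower, 7 and 0 higher and 15 and 13 not past the threshold in the paired fit, where neither list was called with an estimated correlation (adjusted p = 0.55 and 0.52). A difference in library size is argued against: both lists were lower in the pair with a half-size to intact ratio of total counts of 1.30 and in the pair with a ratio of 0.69. A uniformly smaller epidermal share stays open. With the 2 shared genes left out, the mean paired log2 fold changes of the remaining 23 multiciliated and 41 epidermis genes, −0.70 and −0.34, differed by −0.37. Resampling genes, not embryos, gave a 95% bootstrap interval of −0.79 to 0.06 and a permutation p = 0.0713 with 100000 resamples. Genes of a list are not independent, so neither value measures the spread between embryos. The interval is also too wide to show an equal fall. With all members, the multiciliated mean was below the epidermis mean in each pair: −0.76 against −0.46, −0.62 against −0.27 and −0.88 against −0.38. In the paired fit 7 epidermis members rose. An earlier stage at collection may also account for the pattern and cannot be told apart from an effect of halving: the early gastrula list had a paired median of 0.45, but the late neurula onset list had a median of −0.10 over 17 members with a standard error of 0.16, which neither excludes a delay nor shows one. An effect of embryo size itself also stays open. Every half-size embryo had been through blastomere separation and the other group was intact, so size and the separation cannot be told apart in these samples. The immediate early and wounding list was higher by camera with the preset correlation (adjusted p = 8.96e-05), with 5 rises and 1 fall in the paired fit. No stage series was analysed here that would separate size or the separation from a delay. The same limits hold for the other changes reported here, those of mmp3.L and of the dorsal-ventral genes included. For these a difference in stage was not tested.

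Homeologs of one gene may respond alike to halving. Of 623 genes called in the paired fit whose other homeolog was tested, 84.8% had a homeolog with the same sign, against a highest value of 56.0% over 1000 random pairings. Both homeologs were called in 107 pairs, against 19.6 for independent lists, and 4 of these had opposite signs: LOC100498004, hyal2, pkp3 and ugp2. Reads shared between homeologs would also give them a common sign, and that was not tested.

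Other groupings of the libraries were too few for a share under 0.05. Without pairing, all 10 of the 10 splits into 3 and 3 called as many genes as the real one, which called 0, with 0 as the highest other value, overall and at 1.5-fold or more. For list calls 2 of the 10 splits, the real one included, reached the real count of 10, and the highest other value was 13, from the split that set intact replicates 1 and 2 and half-size replicate 2 against the rest and so kept pairs 2 and 3 together. Among the splits that part all 3 pairs, the highest other count of lists without pairing was 7. Among the 4 splits that part all 3 pairs, the paired fit called 1283 genes for the real one and at most 0 for the other 3 (1 of 4 splits), 776 against at most 0 at 1.5-fold or more (1 of 4), and 13 lists against at most 8 (1 of 4). Camera with the preset correlation therefore called lists under wrong groupings too, in every split tried. Switching 1 of the 3 pairs leaves part of the real contrast, and splits that keep pairs together set replicates apart. The list calls under these groupings are thus not a count of false calls.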
